A study of Homo sapiens with 12 samples.

How the data were processed

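MCF7 is an established human breast cancer cell line of the luminal, oestrogen receptor positive kind that is known to carry p53 of normal sequence. The samples were 12 arrays of total RNA from 2 MCF7 lines, each without irradiation and 4 hours after 20 Gy of X-rays, with 3 arrays in each of the 4 groups. The first was a control line. The other was made with CRISPR, an enzyme system that cuts DNA at a chosen place, to remove the p53β splice form, and is called the βCRISPR line here. p53β is made from the TP53 gene by splicing in an alternative last exon, which gives the protein a different C-terminal end. The group of each array was taken from its title and source name. For the 3 irradiated βCRISPR arrays the genotype label reads wild type, against the title and source name, and an expression check of this conflict is given in the closing section. The labels number the replicates but do not say that they are separate cultures, so every p-value measures only the spread between these arrays. Each genotype was represented by a single line. No comparison between the lines, the difference in response included, can therefore part an effect of the edit from other differences between these lines.

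Per the labels, the RNA was labelled with the GeneChip WT Plus kit and hybridised to an Affymetrix array that holds probe sets for single exons and for exon junctions. The authors processed the arrays with Affymetrix Expression Console, Transcriptome Analysis Console 3.0 and RMA, which subtracts background, gives the probe signals of all arrays the same distribution and summarises the probes of a probe set. The deposited values are probe set signals in log2 units. The scale is not written in the table. It was read from the values, which ran from 2.20 to 15.3 with array medians between 6.78 and 6.86, as log2 signals do. Since RMA gives arrays equal distributions, a change shared by most transcripts would not show. The signal depends on each probe's binding as well as on RNA abundance, so levels of different genes are not comparable and large changes tend to be compressed.

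The table holds 914585 probe sets, of which 573909 are exon, 339146 junction and 1530 control probe sets. The probe annotation used here pairs 672085 of them with 1 gene symbol and 39483 with several symbols, and names no gene for 203017. Of 22085 symbols, 22014 matched a current symbol or a synonym of 1 gene. The genome build of the probe design is not stated in the sources used here, so no genome positions are given. A probe set was kept if its mean over the 12 arrays was above the median of all probe set means (6.81 log2 units), which left 457292, of which 370193 had 1 gene symbol. Probe sets with several symbols or none were left out of gene values. A gene needed 3 kept probe sets, and its value was the array effect plus the overall level of a Tukey median polish with at most 20 iterations. This gave 16160 genes. No detection calls were used.

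Gene values were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, empirical Bayes moderation and a Benjamini-Hochberg adjusted p under 0.05. All p-values are two-sided. The 5 comparisons were irradiation in the control line, irradiation in the βCRISPR line, βCRISPR against control without irradiation, the same after irradiation, and the difference between the 2 irradiation responses (βCRISPR minus control). Each kept probe set was compared in the same way. Exon usage, the change of a probe set against the other probe sets of its gene, was tested with diffSplice of limma and a Simes p per gene. A splicing index, each probe set minus its gene's value on the same array, was tested as well; this was added after the simulation below. Tables were read with the R package data.table (1.17.8) and matrixStats 1.5.0, and figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

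The design, the gene lists and the rule for named genes were set before the data were examined. The rule names, for each comparison, the 10 largest increases and 10 largest decreases among genes past the threshold whose arrays do not overlap between the groups (overlap was not asked of the difference in response), up to 4 members of each list with the smallest p, and always TP53, CDKN1A and MDM2. Loci without an approved-style symbol, pseudogenes among them, are counted but not picked for the 10 largest changes. For exon usage it names the 8 genes with the smallest p, and TP53 and MDM2. Of 23 lists, 3 hold p53 targets (cell cycle and feedback, apoptosis, DNA repair and metabolism). The others hold mitotic genes, G1/S and replication genes, replication-dependent histones, double-strand break repair, immediate early genes, NF-kB targets, senescence markers, interferon-stimulated genes, the unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol synthesis, oestrogen receptor targets, splicing factors, mesenchymal, luminal, basal and immune cell markers, cytosolic ribosomal proteins, mitochondrially encoded genes and reference genes. Of the mitochondrially encoded genes 0 had a gene value, so that list was not tested. Some genes stand in more than 1 list, among them 10 of the 31 oestrogen receptor targets and 8 of the 25 luminal markers. Lists were tested with camera of limma, which compares a list with all other genes, with the inter-gene correlation preset at 0.01. Camera with an estimated correlation and fry were the alternatives.

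The pipeline was tested on simulated data. With 50 of 16160 genes shifted at each step, 32% were recovered at 1.2-fold, 88% at 1.5-fold, 98% at 2-fold and 100% at 3-fold, and 0.0564% of unchanged genes were called. The noise was drawn separately for each probe set and gene, with no part shared by all genes of an array. The real arrays have such a part, the array gradient described below, so these shares may not hold for them. DiffSplice found 92% of genes with 1 shifted probe set but also called 6.38% of unchanged genes. The splicing index found 59% and called 0.0444%, so exon usage is reported with both counts. The number of arrays limits the precision: the median SE of a log2 change was 0.0671, and 0.0949 for the difference in response.

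Replicate numbers were checked for pairing. Of 18 pairs of arrays with the same number in different groups, 5 had deviations from their group means that correlated above 0.1. Of 12 arrays, 3 correlated best with an array of their own number, so the numbers were not used to pair arrays. Of the variance of these deviations 56.6% lay along the array gradient described below, and the check was not repeated without it. It therefore cannot show whether equal numbers were handled together. Alternatives tried were quantile normalization, median centring, no filter, a filter at the 75th percentile, the mean of probe sets in place of the median polish, exon probe sets only, an intensity trend with a robust prior, array quality weights, a replicate block, fits of the compared groups only, a 1.5-fold minimum and leaving out each array. After the data had been seen, fits without probe sets of alternative haplotype sequences, without the 2 arrays at the ends of an array gradient, and with that gradient removed were added. The array gradient is the main component of the arrays' deviations from their group means. It was removed by taking each array's score along it, measured from the mean of all 12 arrays, out of all genes. Differences between groups that lie along it were thus removed as well.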

Results

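The expression of exons, exon junctions and whole genes was measured in 12 arrays, 3 each from unirradiated control cells, irradiated control cells, unirradiated βCRISPR cells and irradiated βCRISPR cells. The series title gives the question as the transcript profile of MCF7 cells without the p53β splice form 4 hours after 20 Gy. Array medians lay between 6.78 and 6.86 log2 units, and the lowest correlation between 2 arrays of the same group was 0.975. The first principal component (47.9% of the variance) parted the lines, and the second (28.4%) parted irradiated from unirradiated arrays. Within groups, 56.6% of the remaining variance lay along 1 direction, the array gradient. Replicate 3 of the unirradiated control group lay at one end (score 20.8), and replicates 3 and 1 of the unirradiated βCRISPR group at the other (-22.5 and -16.0). Because these arrays belong to unirradiated groups of different lines, values with the gradient removed are given beside the gene lists whose call was gained or lost with it. The mean of 23 background probe sets lay between 5.76 and 5.88 log2 units across arrays. For values at or below this background only the direction of a change and the level are given, where the size depends on them. Values above it can also be unspecific signal. PTPRC, an immune cell marker that MCF7 cells are not expected to express, lay between 7.01 and 7.40. Folds from low levels, such as those of SERPINB5, FAS and LXN below, may thus be inexact.

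TP53, the gene edited in the βCRISPR line, had 0 named probe sets in the annotation used here. The edit itself was therefore not checked, and neither the p53β exon nor total TP53 expression is reported.

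Irradiation of the control line raised p53 target genes and lowered genes of mitosis. SERPINB5, which encodes the serpin maspin, rose 9.87-fold (log2 change 3.30, SE 0.10, n = 3 arrays per group, limma adjusted p = 2.2e-10), from a mean of 6.24 ± 0.13 (SD) to 9.54 ± 0.15 log2 units. TP53INP1, a p53-induced nuclear protein, rose 8.48-fold, the death receptor gene FAS 7.23-fold, and GDF15, a secreted stress cytokine, 6.03-fold. The largest decrease was that of PLK1, a kinase that drives mitosis, at 3.61-fold (log2 change -1.85, SE 0.06, limma adjusted p = 3.51e-10). KIF23, a kinesin of cytokinesis, fell 2.97-fold, and CENPE, a motor of the kinetochore, fell 2.85-fold.

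**Figure D1:**
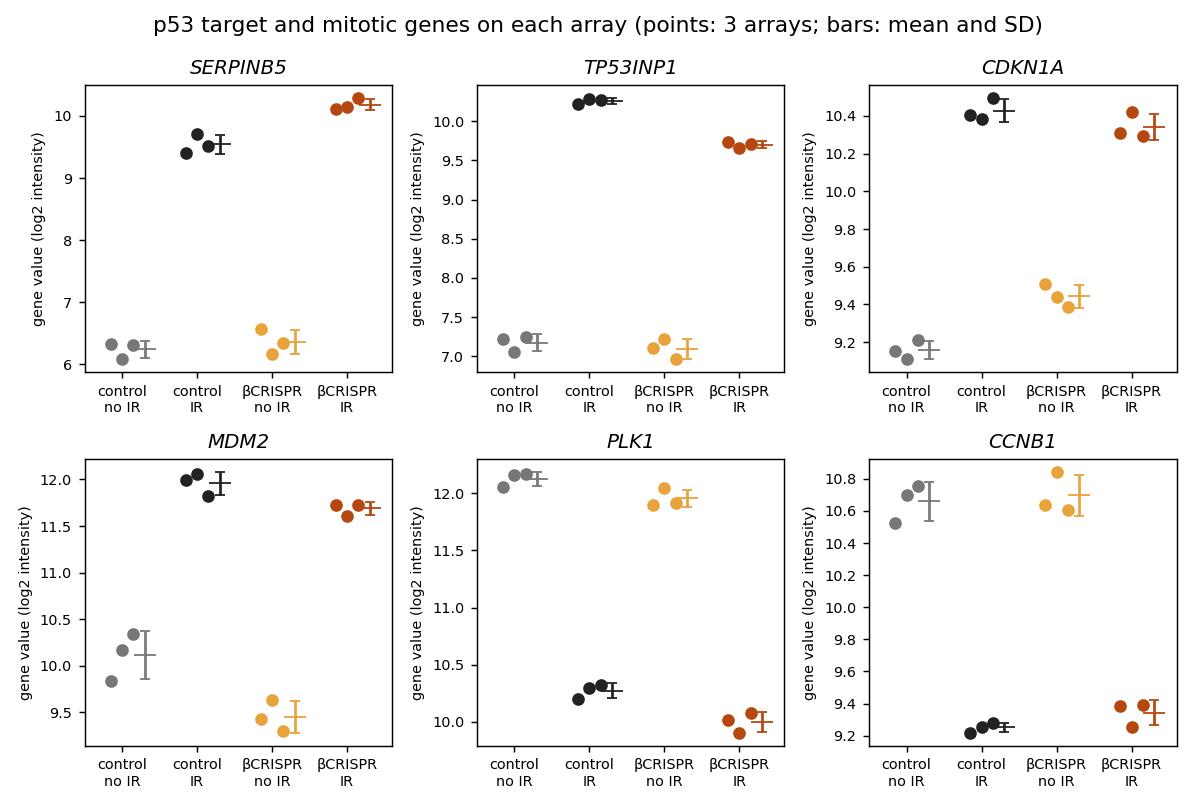
Gene values (log2 intensity, vertical axes) of SERPINB5, TP53INP1, CDKN1A, MDM2, PLK1 and CCNB1 in the 4 groups; points are the 3 arrays of a group and bars give the mean and SD. In both lines all irradiated arrays lie above the unirradiated ones for the 4 p53 targets and below them for PLK1 and CCNB1.

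All 3 lists of p53 targets rose in the control line. Of 27 measured targets of the cell cycle and of p53 feedback, 23 rose and 0 fell (23 and 0 adjusted over the list alone), with a camera adjusted p of 5.26e-47 (adjusted p = 0.000179 with an estimated correlation). Among them were SESN1, a sestrin that restrains growth signalling (log2 change 2.49), the antiproliferative gene BTG2 (2.33), MDM2, which encodes the ligase that degrades p53 (1.84), and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (1.27). Of 23 apoptotic targets, 15 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 2.36e-23, and adjusted p = 0.000179 with an estimated correlation). They included FAS (2.85), C12orf5, now named TIGAR, a regulator of glycolysis (1.61), TP53I3 (1.35) and the death receptor gene TNFRSF10B (1.06). Of 21 targets in DNA repair and metabolism, 13 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 5.38e-13, and adjusted p = 0.00045 with an estimated correlation). Examples were the translesion polymerase gene POLH (1.83), the nucleotide excision repair genes XPC (1.35) and DDB2 (1.22), and the ribonucleotide reductase gene RRM2B (1.19).

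Of 39 measured mitotic genes, 38 fell and 0 rose (39 and 0 adjusted over the list alone; camera adjusted p = 3.71e-63, and adjusted p = 0.00982 with an estimated correlation). Besides PLK1 these included KIF20A (-1.42), CDC20, an activator of the anaphase-promoting complex (-1.42), and the cyclin gene CCNF (-1.03). Of 38 G1/S and replication genes, 18 fell and 2 rose (26 and 3 adjusted over the list alone; camera adjusted p = 2.7e-12, but adjusted p = 0.239 with an estimated correlation). MCM10, which helps to load the replication machinery, changed by -0.50, UHRF1, a reader of hemimethylated DNA, by -0.37, and TYMS, which makes thymidylate, by 0.47. The 3 lists of p53 targets and the mitotic list were the 4 list calls in the control line that held with an estimated correlation. No other list call in this line did.

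Immediate early genes moved apart: of 27, 8 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00166, and adjusted p = 0.397 with an estimated correlation). EGR1, a zinc finger factor induced by stress kinases, rose by 1.06 and IER3 by 0.56, while MYC, a driver of growth, fell by 0.93 on the log2 scale. Of 29 hypoxia and glycolysis genes, 6 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 3.97e-05, and adjusted p = 0.368 with an estimated correlation). The hexokinase gene HK2 changed by -0.72 and the glucose transporter gene SLC2A1 by -0.28. Of 24 luminal markers, 7 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.000635, and adjusted p = 0.332 with an estimated correlation). They included the transcription factor genes TFAP2C (-0.49), SPDEF (-0.45) and GRHL2 (-0.41). Of 30 oestrogen receptor targets, 8 fell and 3 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.0202, and adjusted p = 0.297 with an estimated correlation). MYB stood at -0.57 and SIAH2 at -0.40. The oestrogen receptor list did not pass without replicate 3 of the unirradiated control group (0.123) or with the array gradient removed (0.0822), where its median did not shrink (-0.04 in place of -0.03).

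Smaller shifts were called in 5 further lists of the control line, none of which held with an estimated correlation. Of 35 splicing factors, 6 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 0.00108, and adjusted p = 0.612 with an estimated correlation), and of 30 double-strand break repair genes 6 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.00575, and adjusted p = 0.605 with an estimated correlation). H2AFX, now H2AX, the histone that marks broken DNA, fell by 0.40 and the exonuclease gene EXO1 by 0.35 on the log2 scale. NF-kB targets (2 of 20 rose, 0 fell; 3 and 0 adjusted over the list alone) had a camera adjusted p of 0.014 (adjusted p = 0.337 with an estimated correlation), with NFKB2 at 0.27. Mesenchymal markers (1 of 23 rose, 0 fell; 1 and 0 adjusted over the list alone) had 0.0353 (adjusted p = 0.618 with an estimated correlation), the member that rose being the smooth muscle actin gene ACTA2 (0.79). Cytosolic ribosomal proteins (1 of 34 rose, 0 fell; 0 and 0 adjusted over the list alone) had 9.82e-05 (adjusted p = 0.505 with an estimated correlation). Without replicate 3 of the unirradiated control group the splicing, repair and mesenchymal calls ended (0.315, 0.377 and 0.377). The repair and mesenchymal calls also ended without replicate 3 of the irradiated control group (0.0889 for both), and the mesenchymal call without its replicate 1 (0.0692). Removing the gradient left the splicing list with 7 genes up and 12 down (0.0889, median -0.07 in place of -0.09), the repair list with 3 and 7 (0.197, median -0.02 in place of -0.06) and the mesenchymal list with 2 and 0 (0.197, median 0.01 in place of 0.06). The ribosomal list then had 14 and 0 (1.88e-07). The remaining lists did not pass: histones (0.133), senescence markers (0.75), interferon-stimulated genes (0.105), unfolded protein response (0.447), cholesterol synthesis (0.746), basal markers (0.142), immune cell markers (0.223) and reference genes (0.48). Without replicate 1 of the unirradiated control group the histone and the interferon lists passed (0.0393 for both). Single members of the lists that did not pass changed, such as HSD17B7, an enzyme of sterol synthesis (0.99), the nuclear lamina gene LMNB1 (-0.53) and DDIT4, an inhibitor of growth signalling (0.47).

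In all, limma called 1400 of 16160 genes in the control line, 460 higher and 940 lower, of which 204 changed by at least 1.5-fold (101 higher, 103 lower). The arrays of the 2 groups did not overlap for 1399 of the 1400, and for 25.1% of all genes against 10% by chance. Without replicate 1 or 2 of the irradiated control group, 877 and 908 genes passed. With the array gradient removed 3635 passed, and with array quality weights, whose estimate did not converge, 5523.

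Irradiation of the βCRISPR line raised p53 target genes and lowered genes of mitosis as well. SERPINB5 rose 14.2-fold (log2 change 3.82, SE 0.10, n = 3 arrays per group, limma adjusted p = 4.09e-11), from 6.36 ± 0.20 (SD) to 10.18 ± 0.09 log2 units. FAS rose 9.28-fold, SESN1 6.13-fold, GDF15 6.11-fold, TP53INP1 6.08-fold and MDM2 4.71-fold. KITLG, the ligand of the receptor KIT, rose 4.38-fold and was among the 10 largest increases in this line. PLK1 fell 3.87-fold (log2 change -1.95, SE 0.06, limma adjusted p = 2.07e-10), CDC20 2.98-fold and CENPE 2.97-fold.

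Of the p53 targets measured in the βCRISPR line, 25 of 27 rose in the cell cycle and feedback list (25 rose and 1 fell adjusted over the list alone; camera adjusted p = 4.72e-34), 16 of 23 in the apoptosis list (16 and 1 adjusted over the list alone; 2.35e-15) and 14 of 21 in the repair and metabolism list (14 and 2 adjusted over the list alone; 5.59e-12). Over all genes 0 members of these lists fell. Each of the 3 calls had an adjusted p of 0.000612 with an estimated correlation, and no other list held there. BTG2 rose by 1.70, EDA2R, a receptor of the TNF family, by 2.12, the autophagy gene DRAM1 by 1.93, POLH by 1.85, DDB2 by 1.62, ACER2, a ceramidase gene, by 1.45 and CDKN1A by 0.90. Of 39 mitotic genes, 36 fell and 0 rose (36 and 0 adjusted over the list alone; camera adjusted p = 1.44e-32, but adjusted p = 0.0633 with an estimated correlation), KIF20A by 1.45, CCNB1, the cyclin of mitotic entry, by 1.35 and HMMR by 1.24 on the log2 scale. Of 38 G1/S genes, 13 fell and 4 rose (18 and 4 adjusted over the list alone; camera adjusted p = 0.0215, and adjusted p = 0.896 with an estimated correlation). Among them MCM2, part of the replicative helicase, changed by -0.25, TYMS by 0.69 and PCNA, the sliding clamp of DNA polymerases, by 0.67. The G1/S call ended without replicate 2 of the unirradiated (0.489) or of the irradiated βCRISPR group (0.0991). With the gradient removed 26 fell and 4 rose (8.02e-11).

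Part of the cholesterol synthesis genes rose in the βCRISPR line: of 21, 7 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.000788, and adjusted p = 0.274 with an estimated correlation). HSD17B7 stood at 1.32, SC5DL, now SC5D, at 0.59 and TM7SF2 at 0.40. Immediate early genes rose in 9 of 27 cases and fell in 1 (11 and 2 adjusted over the list alone; camera adjusted p = 0.0039, and adjusted p = 0.542 with an estimated correlation). EGR1 stood at 1.17, IER3 at 0.50 and MYC at -0.45. In the unfolded protein and integrated stress response 6 of 27 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0197, and adjusted p = 0.288 with an estimated correlation). DDIT4 changed by 0.98, HERPUD1, which takes part in protein degradation at the endoplasmic reticulum, by 0.38 and the pseudokinase gene TRIB3 by -0.29. Ribosomal proteins rose in 10 of 34 cases with 0 falling (17 and 0 adjusted over the list alone; camera adjusted p = 1.65e-08, and adjusted p = 0.427 with an estimated correlation), and with the gradient removed in 13 of 34 (4.13e-05, list median 0.07 in place of 0.14). Reference genes rose in 5 of 15 cases and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00517, and adjusted p = 0.638 with an estimated correlation). The polymerase subunit gene POLR2A stood at 0.32 and B2M at 0.39, and with the gradient removed 4 rose and 3 fell (0.342). Of 20 immune cell markers, which MCF7 cells are not expected to express, 4 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.00926, and adjusted p = 0.701 with an estimated correlation), by -0.23 to -0.29 on the log2 scale from levels of 7.34 to 8.11; with the gradient removed 2 fell and 1 rose (0.231). The stress response list no longer passed with the gradient removed (7 up, 4 down, 0.172), although its median was 0.03 either way.

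The other lists did not pass in the βCRISPR line: histones (0.555), double-strand break repair (0.389), NF-kB targets (0.547), senescence markers (0.547), interferon-stimulated genes (0.759), hypoxia and glycolysis (0.544), oestrogen receptor targets (0.98), splicing factors (0.544, camera up), mesenchymal (0.136), luminal (0.981) and basal markers (0.555). With the gradient removed the splicing list passed in the opposite direction, with 16 of 35 down and 4 up (0.00827). Without replicate 2 of the unirradiated βCRISPR group the repair and mesenchymal lists passed (0.0453 and 0.0266). Among their members HK2 changed by -0.57, LMNB1 by -0.63, H2AFX by -0.34, the progesterone receptor gene PGR by 0.63, the splicing kinase gene CLK1 by 0.64 and ACTA2 by 1.13, the last of which did not pass with the filter at the 75th percentile. In all, limma called 3381 genes in the βCRISPR line, 1893 higher and 1488 lower, of which 250 changed by at least 1.5-fold (177 higher, 73 lower). The groups did not overlap for 3273 of the 3381, and for 40.9% of all genes against 10% by chance. Leaving out 1 array moved the count to 1621, 7182 and 1599 (replicates 1, 2 and 3 of the unirradiated βCRISPR group) and to 1625, 2071 and 1681 (replicates 1, 2 and 3 of the irradiated one). It was 2229 without the 2 arrays at the ends of the gradient and 11545 with array quality weights, where 36.8% of the called genes were higher in place of 56.0%.

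Across the 16160 genes the log2 changes of the 2 lines had a Pearson correlation of 0.563 and a Spearman correlation of 0.169, and 48.9% had the same sign; genes are not independent replicates, so no p is given. The Pearson value was 0.788 with the gradient removed. Among the 302 genes called at 1.5-fold or more in either line, 98.7% had the same sign in both, the Pearson correlation was 0.957, and the median ratio of the βCRISPR over the control change was 1.16. Of 878 genes called in both lines, 391 rose in both, 483 fell in both and 4 moved in opposite directions, against 53.9 and 86.6 shared increases and decreases for independent calls.

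**Figure D2:**
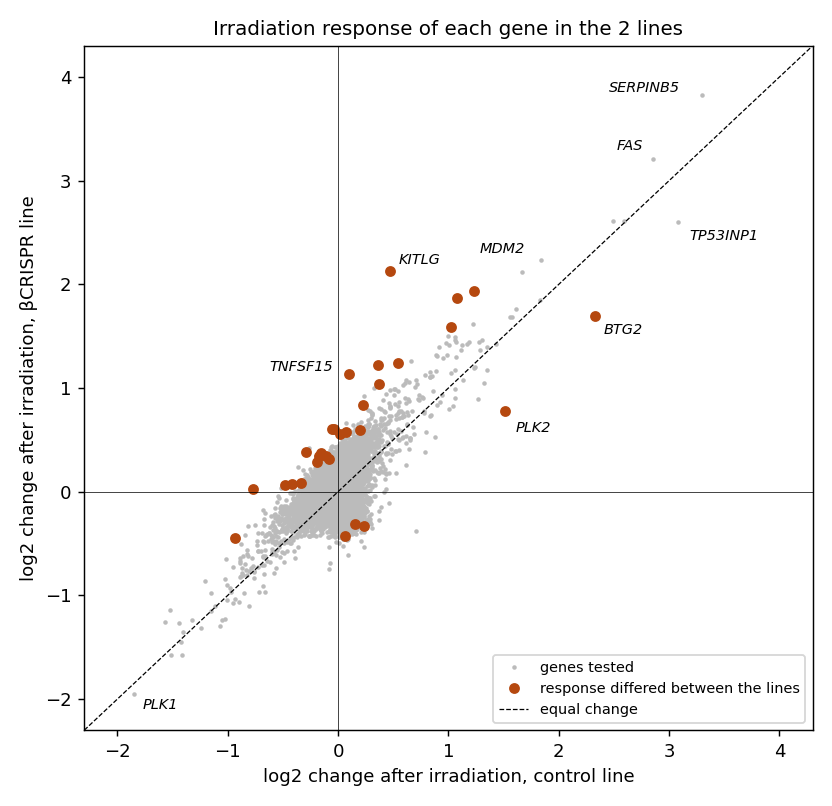
Log2 change after irradiation in the control line (horizontal axis) against that in the βCRISPR line (vertical axis), 1 point per gene; the dashed line marks equal change and the large points the 30 genes whose response differed between the lines. PLK1 lies near the line of equal change and KITLG far above it. SERPINB5 (3.30 in the control line, 3.82 in the βCRISPR line) and FAS (2.85 and 3.21) lie somewhat above it without a called difference. The control values of TNFSF15 lie below the background.

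The difference between the 2 responses was called for 30 genes, 25 with a more positive change in the βCRISPR line and 5 with a more negative one. The count was 411 with the array gradient removed and 9710 with array quality weights. KITLG rose 4.38-fold in the βCRISPR line, from a level far below that of the control line, and had a log2 change of 0.47 in the control line (difference 1.66, SE 0.11, n = 3 arrays per group, limma adjusted p = 1.14e-05). TNFSF15, a cytokine of the TNF family, rose by 1.13 in the βCRISPR line (difference called with a limma adjusted p of 0.000166). Its control line values (4.77 and 4.87) lay below the background, so its change there could not be measured. WDR63, now DNAI3, an axonemal dynein chain, differed by 0.86, and BAMBI, a pseudoreceptor that dampens TGF-β signalling, by 0.79, with a change of -0.77 in the control line and of 0.02, which did not pass, in the βCRISPR line. The p53 targets PLK2, a stress-induced kinase, and BTG2 rose less in the βCRISPR line, with differences of -0.73 and -0.63, while the p53 target DRAM1 rose more (0.70). Their levels already differed without irradiation: PLK2 stood at 8.40 in the βCRISPR line against 6.82 in the control line, BTG2 at 9.01 against 8.54 and DRAM1 at 8.04 against 8.64. After irradiation PLK2 was still higher (9.18 against 8.33), while BTG2 (10.71 against 10.87) and DRAM1 (9.97 against 9.88) lay closer together.

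Of the 30 genes, 11 were called in the βCRISPR line alone, 4 in the control line alone and 15 in both, 3 of these in opposite directions. HERPUD1 was called down in the control line (-0.29) and up in the βCRISPR line (0.38), with a difference of 0.67. MYC fell in both lines and fell less in the βCRISPR line (difference 0.49). The others that the naming rule picked among the largest differences were the cadherin gene CDH10 (0.70), the kinase gene RPS6KA5 (0.66), BPGM, an enzyme of red cell glycolysis (0.64), and CPEB4, which regulates translation (0.61), and, on the negative side, MLN (-0.56), TSHZ3 (-0.49) and MIA (-0.47). By its limits on symbols the rule passed over the pseudogene XGPY2 (0.79) and the gene KIAA1217 (0.67). CDKN1A (-0.37, adjusted p = 0.0951 by limma), MDM2 (0.39, 0.194), TP53INP1 (-0.48, 0.0777) and FAS (0.36, 0.159) did not pass. KITLG passed in every alternative and TNFSF15 in each that measured it; WDR63 did not pass with the mean of probe sets, nor BAMBI without the filter. The calls of PLK2, BTG2, DRAM1, HERPUD1 and MYC each ended without any 1 of replicates 1, 2 and 3 of the irradiated control group or replicates 1 and 2 of the irradiated βCRISPR group. Those of DRAM1, HERPUD1 and MYC also ended without replicate 3 of the latter group. With a replicate block the calls of BTG2, DRAM1, HERPUD1 and MYC ended too, as did those of CDH10, RPS6KA5, BPGM, MLN, TSHZ3 and MIA. The latter calls and that of CPEB4 also ended without the arrays at both ends of the gradient. BPGM did not pass with quantile normalization or median centring either. The call of DRAM1 ended with exon probe sets only, and that of PLK2 without the filter. MYC did not pass without the filter, with the mean of probe sets or without the arrays at both ends of the gradient. Without replicate 1 of the unirradiated βCRISPR group the calls of PLK2, BTG2, DRAM1 and MYC ended, and without its replicate 3 those of DRAM1 and MYC. BTG2 did not pass without any 1 of replicates 1, 2 and 3 of the unirradiated control group, nor MYC without its replicate 2 or 3. Of the 30 genes 10 kept their call with a replicate block, 9 without the filter, 13 without the arrays at both ends of the gradient, and 7 to 30 when 1 array was left out. The count itself was 16 without replicate 3 of the unirradiated control group and 15, 3640 and 18 without replicates 1, 2 and 3 of the unirradiated βCRISPR group. It was 7, 9 and 7 without replicates 1, 2 and 3 of the irradiated control group, and 8, 7 and 13 without those of the irradiated βCRISPR group.

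Camera called 13 lists for the difference in response, 11 towards more positive changes in the βCRISPR line and 2 towards more negative ones, and 0 of them passed with an estimated correlation (lowest adjusted p = 0.323 with an estimated correlation). The smallest values were those of cholesterol synthesis (0.000998), immune cell markers (0.00122), splicing factors (0.00158) and double-strand break repair (0.0022). Over all genes 0 members of these 4 lists passed in limma, where 3786 genes had an unadjusted p under 0.05; adjusted over the list alone 2 of 21, 0 of 20, 2 of 35 and 0 of 30 did. Mitotic genes did not pass as deposited (0.473, median 0.00), but did without replicate 1 of the unirradiated control group (0.0367, camera up). With the gradient removed they had the smallest value of all lists (2.14e-10, camera down), with 10 of 39 more negative in the βCRISPR line, 1 more positive and a median of -0.17. That fit was chosen after the data were seen and was run only with the preset correlation of 0.01. The estimated correlation of the mitotic list as deposited was 0.475, so the small value is to be read with caution. Of the p53 targets, the lists of the cell cycle (0.747) and of apoptosis (0.473) did not pass. That of DNA repair and metabolism did as deposited (0.0101, with 5 of 21 more positive adjusted over the list alone; adjusted p = 0.323 with an estimated correlation), but not with the gradient removed (0.0664, median 0.04 in place of 0.11). The calls that held after this removal were those of cholesterol synthesis (0.0138, median 0.06 in place of 0.13), the stress response (0.0252, median 0.05 in place of 0.08) and hypoxia and glycolysis (0.0252, median 0.06 in place of 0.04), and immediate early genes came to pass (0.0244 in place of 0.473). The other calls ended: immune cell (0.0563), mesenchymal (0.395) and luminal markers (0.433), oestrogen receptor targets (0.464) and, with the direction turned, G1/S genes (0.2), splicing factors (0.238), repair (0.464), ribosomal proteins (0.464) and reference genes (0.605).

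Without irradiation the largest differences between the lines were those of TNFSF15 and SLC6A14, an amino acid transporter. With a single line of each genotype, the line differences given here and below cannot be assigned to the edit. TNFSF15 was higher in the βCRISPR line (limma adjusted p = 3.62e-15, n = 3 arrays per group), with 9.93 log2 units against 4.77 in the control line, and SLC6A14 with 9.47 against 5.69. Both control values lay below the background, so no fold is given. LXN, an inhibitor of carboxypeptidases, was 6.44-fold higher, BST2, the antiviral factor tetherin, 5.94-fold, and DKK1, an inhibitor of Wnt signalling, 4.25-fold. GRPR, the receptor of gastrin-releasing peptide, was 4.00-fold higher. UNC5C, a netrin receptor, was 7.80-fold lower (log2 difference -2.96, SE 0.07, limma adjusted p = 1.32e-11), ERBB4, a receptor of the EGF receptor family, 6.74-fold lower and KITLG 5.10-fold lower. The tight junction gene CLDN1 (1.94), NCAM2 (1.90), the protease gene PRSS23 (1.73) and NRP1 (1.65) completed the largest positive differences. On the negative side stood FAM5C, now BRINP3 (-2.25), S100A14 (-2.06), the sulphate transporter gene SLC26A2 (3.99-fold lower), the lipid transporter gene ABCA12 (-1.83), SYT17 (-1.81), CYP4F22 (-1.56) and the retinoic acid carrier gene CRABP2 (-1.49); SYT17 did not pass with the filter at the 75th percentile.

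**Figure D3:**
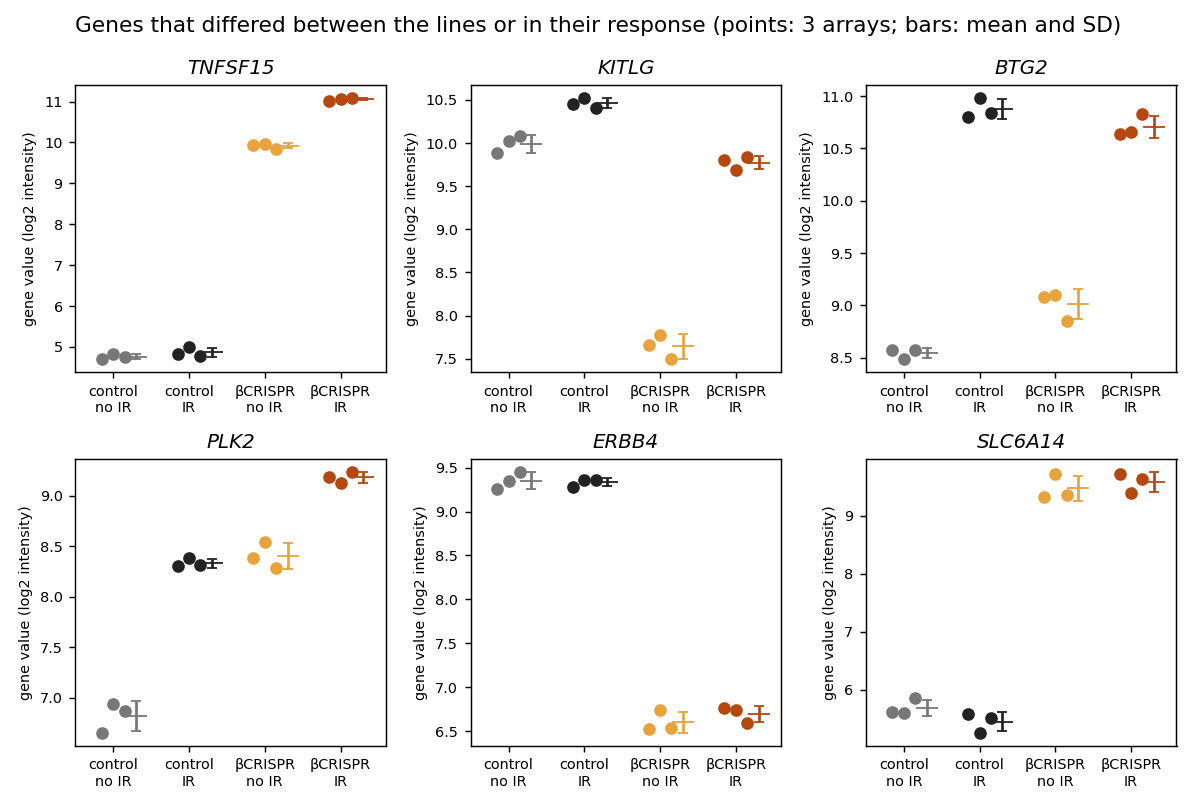
Gene values (log2 intensity, vertical axes) of TNFSF15, KITLG, BTG2, PLK2, ERBB4 and SLC6A14 in the 4 groups; points are the 3 arrays of a group and bars give the mean and SD. TNFSF15 and SLC6A14 are higher and ERBB4 lower in the βCRISPR line in both conditions, and KITLG rises from 7.64 to 9.77 in that line after irradiation.

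After irradiation TNFSF15 (11.06 against 4.87 log2 units, n = 3 arrays per group, limma adjusted p = 3.29e-16) and SLC6A14 (9.59 against 5.45) were again higher in the βCRISPR line, with control values below the background. The same comparison gave LXN at 3.04, BST2 at 2.89, DKK1 at 2.78 and GRPR at 2.48. UNC5C stood at -2.72, ERBB4 at -2.64, S100A14 at -2.04, SLC26A2 at -1.85 and FAM5C at -1.83. SLC27A2, a fatty acid transporter (1.72), and ANXA9 (-1.37) and GSTM3 (-1.35) were among the 10 largest differences in this condition. Across genes the differences with and without irradiation had a Pearson correlation of 0.724 and a Spearman correlation of 0.521, which share no array. Both comparisons called 2336 genes, 873 higher and 1449 lower in both and 14 in opposite directions, against 394.5 and 337.1 for independent calls.

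Hypoxia and glycolysis genes were lower in the βCRISPR line. Without irradiation 19 of 29 were lower and 1 higher (21 and 1 adjusted over the list alone; camera adjusted p = 1.51e-07, and adjusted p = 0.51 with an estimated correlation). Examples were the aldolase gene ALDOC (-0.85), BNIP3, a gene of mitophagy (-0.80), the histone demethylase gene KDM3A (-0.71) and the phosphofructokinase gene PFKP (-0.43). After irradiation 15 were lower and 1 higher (20 and 1 adjusted over the list alone; camera adjusted p = 4.42e-08, and adjusted p = 0.485 with an estimated correlation), with ALDOC at -0.86. After removal of the gradient 24 and 21 were lower. Of the cholesterol synthesis genes 10 of 21 were higher and 2 lower without irradiation (10 and 2 adjusted over the list alone; camera adjusted p = 0.0187, and adjusted p = 0.53 with an estimated correlation), and 15 higher and 1 lower after it (15 and 1 adjusted over the list alone; camera adjusted p = 1.81e-09, and adjusted p = 0.0573 with an estimated correlation). HMGCS1, an early enzyme of the pathway, stood at 0.65 and 1.02, and its regulator SREBF2 at 0.39 and 0.41, while CYP51A1 was lower without irradiation (-0.68). The cholesterol call without irradiation ended without replicate 1 of the unirradiated control group (0.0641) or replicate 2 of the unirradiated βCRISPR group (0.109). After removal of the gradient it stood at 4.81e-05, with 16 higher and 3 lower. The 5 measured replication-dependent histones of 32 listed were all lower in both conditions (5 adjusted over the list alone; camera adjusted p = 0.000128 and 2.43e-05, and adjusted p = 0.176 and 0.0573 with an estimated correlation). HIST1H2AC stood at -1.43 and -1.05 and HIST1H2BK at -0.61 and -0.54.

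Part of the cell cycle genes was lower in the βCRISPR line, and without irradiation these calls ended with the array gradient removed. Of 39 mitotic genes, 18 were lower and 1 higher without irradiation (19 and 1 adjusted over the list alone; camera adjusted p = 1.5e-05, and adjusted p = 0.609 with an estimated correlation) and 15 lower and 1 higher after it (22 and 2 adjusted over the list alone; camera adjusted p = 1.26e-05, and adjusted p = 0.956 with an estimated correlation). AURKB, a kinase of chromosome segregation, stood at -0.43 and -0.60. After removal of the gradient 15 were lower and 9 higher without irradiation (0.655), and 26 lower and 6 higher after it (1.7e-05). Of 38 G1/S genes, 22 were lower and 4 higher without irradiation (23 and 5 adjusted over the list alone; camera adjusted p = 1.45e-05, and adjusted p = 0.53 with an estimated correlation) and 14 and 4 after it (15 and 4 adjusted over the list alone; camera adjusted p = 0.00641, and adjusted p = 0.956 with an estimated correlation). MCM3, part of the replicative helicase, stood at -0.48 in both conditions and the polymerase subunit gene POLE2 at -0.92 without irradiation. The 2 values without the gradient were 0.117 and 0.00649, and the call after irradiation ended without replicate 2 of the irradiated control group (0.072).

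Further list calls between the unirradiated lines ended with the array gradient removed, and 0 of them held with an estimated correlation. Interferon-stimulated genes (14 of 29 higher, 1 lower; 17 and 1 adjusted over the list alone) had a camera adjusted p of 0.00234 (adjusted p = 0.53 with an estimated correlation) and 0.0765 with the gradient removed, with BST2 at 2.57 and PARP9 at 0.40. Mesenchymal markers (13 of 23 higher, 0 lower; 13 and 0 adjusted over the list alone) had 0.00243 (adjusted p = 0.609 with an estimated correlation); with the gradient removed 3 were higher and 1 lower (0.575), and the matrix protein gene FN1 stood at 1.00. Double-strand break repair genes (14 of 30 lower, 3 higher; 15 and 3 adjusted over the list alone) had 0.00219 (adjusted p = 0.609 with an estimated correlation) and 0.853 with the gradient removed, with PRKDC, the catalytic subunit of DNA-dependent protein kinase, at -0.59. Splicing factors (9 of 35 lower, 2 higher; 8 and 2 adjusted over the list alone) had 0.0029 (adjusted p = 0.652 with an estimated correlation), and with the gradient removed the direction was the opposite (8 lower, 13 higher, 0.575). The p53 targets of repair and metabolism (8 of 21 lower, 2 higher; the same counts adjusted over the list alone) had 0.022 (adjusted p = 0.363 with an estimated correlation) and 0.267 with the gradient removed. The values for the unfolded protein response (11 of 27 lower, 4 higher; the same counts adjusted over the list alone) were 0.0338 (adjusted p = 0.53 with an estimated correlation) and 0.434, although its median did not shrink (-0.06 as deposited, -0.08 with the gradient removed). Those for ribosomal proteins (7 of 34 lower, 0 higher; 3 and 0 adjusted over the list alone) were 0.00529 (adjusted p = 0.652 with an estimated correlation) and 0.936. Those for reference genes (7 of 15 lower, 2 higher; 8 and 2 adjusted over the list alone) were 0.00545 (adjusted p = 0.609 with an estimated correlation) and 0.655.

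Other lists did not pass between the lines. The p53 targets of the cell cycle had 7 of 27 higher and 7 lower without irradiation (0.753) and 5 higher and 4 lower after it (0.876), and those of apoptosis 6 and 5 of 23 (0.798) and 2 and 2 (0.762). Single targets differed: without irradiation PLK2 stood at 1.58, TP53I3 at 0.69, CCNG1 at -0.73, MDM2 at -0.66 and CDKN1A at 0.29. The CDKN1A call did not hold with the filter at the 75th percentile or with the mean of probe sets. After irradiation CDKN1A stood at -0.09 (limma adjusted p = 0.385) and MDM2 at -0.27 (0.137). The values without and after irradiation were 0.753 and 0.154 for immediate early genes, 0.329 and 0.952 for NF-kB targets, 0.97 and 0.238 for senescence markers, 0.925 and 0.111 for oestrogen receptor targets, 0.0602 and 0.876 for luminal markers, 0.806 and 0.193 for basal markers and 0.0602 and 0.268 for immune cell markers. Luminal and immune cell markers passed without irradiation when replicate 1 of the unirradiated control group (0.0363 and 0.0353) or replicate 2 of the unirradiated βCRISPR group (0.0312 for both) was left out. Members of these lists that differed in both conditions were IGFBP5, a binding protein of insulin-like growth factors (1.37 and 1.42), the glycoprotein hormone gene STC1 (-1.43 and -1.30), TGFB1 (-0.70 and -0.73), AGR2, a luminal disulphide isomerase (1.33 and 1.17), the hyaluronan receptor gene CD44 (-1.19 for both) and the actin bundling gene LCP1 (-0.94 and -0.84). After irradiation, splicing factors (0.808), double-strand break repair (0.447), the stress response (0.876), mesenchymal markers (0.729), ribosomal proteins (0.507), reference genes (0.229), the p53 targets of repair and metabolism (0.808) and interferon-stimulated genes (0.0554) did not pass. The interferon list passed there when replicate 1 (0.0324) or 3 (0.0419) of the irradiated control group or replicate 3 of the irradiated βCRISPR group (0.0176) was left out.

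In several lists whose values did not pass, the median, the mean and the camera direction differed in sign, with medians and means close to 0. Examples are cholesterol synthesis after irradiation of the control line (median -0.01, mean 0.03, camera down), senescence markers after irradiation of the βCRISPR line (median -0.09, mean 0.04, camera down), and oestrogen receptor targets between the unirradiated lines (median 0.02, mean 0.05, camera down).

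In all, limma called 7974 genes between the lines without irradiation (4515 higher and 3459 lower in the βCRISPR line) and 2987 after irradiation (1412 higher, 1575 lower). At 1.5-fold or more there were 468 (93 higher, 375 lower) and 293 (148 higher, 145 lower), and with the gradient removed 309 (132 higher, 177 lower) and 292. Groups did not overlap for 6499 of the 7974 and 2983 of the 2987 genes, and for 46.8% and 39.4% of all genes against 10% by chance. With the gradient removed the counts were 6746, of which 45.2% were higher in place of 56.6%, and 5456; without the 2 arrays at its ends the first was 3286. The first count was 4718 without replicate 3 of the unirradiated control group, 5077 and 4492 without replicates 1 and 3 of the unirradiated βCRISPR group, 4086 when fitted to the 2 groups alone, and 14036 with array quality weights.

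**Figure D4:**
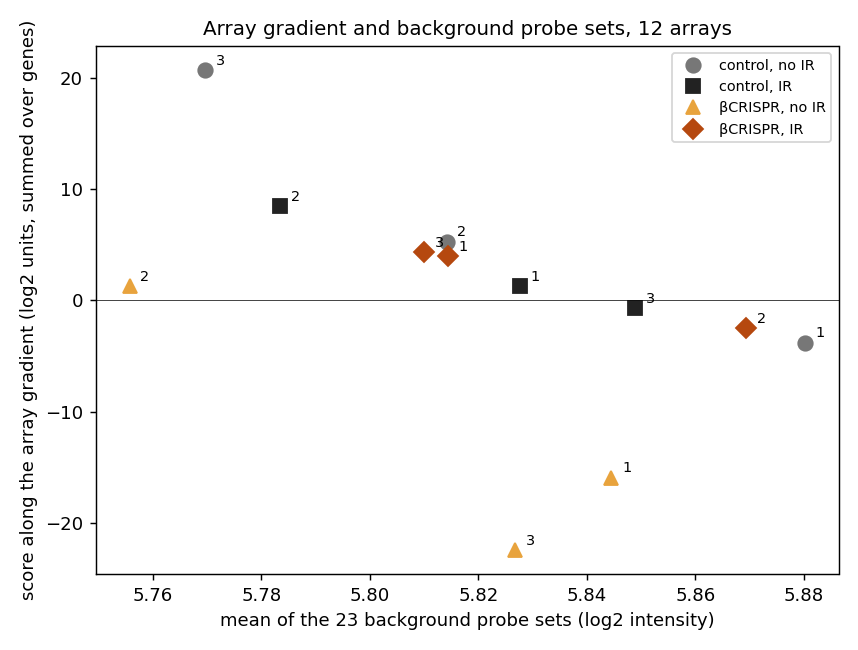
Mean of 23 background probe sets (log2 intensity, horizontal axis) and score along the array gradient (vertical axis) of the 12 arrays, with replicate numbers beside the points. The scores of replicate 3 of the unirradiated control group (20.8) and of replicates 3 and 1 of the unirradiated βCRISPR group (-22.5 and -16.0) lie farthest from 0.

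Probe sets within a gene did not all change alike. In CDKN1A a junction probe set (JUC06002392.hg.1) rose by 3.37 (SE 0.18) in the control line and by 4.01 in the βCRISPR line, against 1.27 and 0.90 for the whole gene. In the control line a junction of PLK3, a stress kinase, rose to 8.28 (JUC01004898.hg.1) and a junction of GRHL3, a factor of epithelial differentiation, to 8.82 (JUC01002496.hg.1), both from levels below the background (5.34 and 5.27). In the βCRISPR line junctions of ANK1 (JUC08007700.hg.1) and LRP1 (JUC12003598.hg.1) rose to 8.46 and 7.86, also from below the background (5.13 and 4.88). There a junction of FDXR (JUC17014046.hg.1, 2.90 against 0.41) and an exon probe set of RASAL1 (PSR12026032.hg.1, 2.19 against 0.13) rose more than their genes. Probe sets of TP53INP1 (JUC08009546.hg.1, 0.13), POLH (JUC06003173.hg.1, -0.12), SERPINB5 (PSR18002587.hg.1, 0.09), FAS (PSR10006964.hg.1, 0.01), BTG2 (PSR01026167.hg.1, 0.01) and MDM2 (PSR12007995.hg.1, -0.06) changed little in the control line although their genes rose. Over the 4 groups that of FAS lay between 12.92 and 12.96, that of SERPINB5 between 10.00 and 10.10 and that of BTG2 between 9.59 and 9.65. Whether such steady signals measure the transcript was not tested.

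Between the lines a junction of AQP3, a water and glycerol channel, was higher without irradiation (12.12 against 5.91) and after it (12.37 against 5.96), the control levels being close to the background (JUC09007233.hg.1). Exon probe sets of UNC13D (PSR17025355.hg.1, -2.96 against -0.11), FOXP2 (PSR07011206.hg.1, 5.72 in the βCRISPR line, below the background, against 8.54) and MFAP2 (PSR01034767.hg.1, -2.84 against -0.25) were lower without irradiation while the genes hardly differed. C18orf1 had an exon probe set at 8.68 against 5.43, the latter below the background (PSR18000821.hg.1), and IPO9 a junction higher by 1.82 against -0.18 (JUC01013773.hg.1). Probe sets of SLC6A14 (PSR0X007509.hg.1, 0.04) and ERBB4 (PSR02043913.hg.1, 0.09) did not follow their genes. After irradiation junctions of SYBU (JUC08010241.hg.1, 9.10 against 5.15, the latter below the background) and SLC7A8 (JUC14005345.hg.1, 2.34 against 0.23 for the gene) were higher, and an exon probe set of TNFSF15 differed by 1.63 (PSR09018974.hg.1). Exon usage of MDM2 was called between the unirradiated lines (diffSplice of limma, adjusted p = 0.00301), with an exon probe set at 0.29 against -0.66 for the gene (PSR12008013.hg.1), and was not called after irradiation (0.882) or for the difference in response (0.804).

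DiffSplice called exon usage in 833 genes for irradiation in the control line, 6116 in the βCRISPR line, 9136 between the unirradiated lines and 2203 between the irradiated lines. In the simulation it called 6.38% of unchanged genes, and 833 is a smaller share of the 16160 genes than that. The count for the control line alone thus cannot show changed exon usage. The splicing index called 182, 733, 4852 and 696, and both methods shared 171, 708, 4547 and 631. Of the diffSplice calls 375, 1742, 4804 and 1124 were also called at gene level, against 72.2, 1280, 4508 and 407 for independent calls. Leaving out 1 array moved the first count to 1434 (replicate 3 of the unirradiated control group) and 451 (replicate 1 of the irradiated control group). The second moved to 3961 and 1833 (replicates 1 and 3 of the unirradiated βCRISPR group) and 3513 (replicate 1 of the irradiated βCRISPR group), the third to 5039 (replicate 3 of the unirradiated βCRISPR group) and the fourth to 1427 (replicate 2 of the irradiated control group). Limma on single probe sets called 10449, 28155, 102966 and 35454 of the 457292 kept. Leaving out 1 array moved the first of these counts to 6527 (replicate 2 of the unirradiated control group) and to 6077, 6106 and 6369 (replicates 1, 2 and 3 of the irradiated control group). The second moved to 12964, 63205 and 11418 without replicates 1, 2 and 3 of the unirradiated βCRISPR group and to 12422, 14059 and 16386 without those of the irradiated one. The third moved to 64875 and 57475 without replicates 2 and 3 of the unirradiated control group, and to 57221 and 47630 without replicates 1 and 3 of the unirradiated βCRISPR group. The fourth moved to 21222, 22277 and 19353 without replicates 1, 2 and 3 of the irradiated control group, and to 22133, 21316 and 21648 without those of the irradiated βCRISPR group.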

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

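The removal of the array gradient, the correlation with background probe sets and the position of the irradiated βCRISPR arrays between the lines were tests chosen after the results were seen. The slope of the line differences, the signal level of the genes and the other splits of the arrays were chosen before.

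The irradiation response differed between the lines in 30 genes by limma, and in 12 of the probe sets tested singly. KITLG had the largest difference on the log2 scale (1.66), taken as the change in the βCRISPR line minus that in the control line. The fitted value for TNFSF15 was 1.03, but its control values lay below the background, so the size of its difference was not measured. WDR63 (0.86), BAMBI (0.79), DRAM1 (0.70), CDH10 (0.70), HERPUD1 (0.67), RPS6KA5 (0.66), BPGM (0.64), CPEB4 (0.61) and MYC (0.49) also had more positive changes in the βCRISPR line. PLK2 (-0.73), BTG2 (-0.63), MLN (-0.56), TSHZ3 (-0.49) and MIA (-0.47) had more negative ones.

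With the array gradient removed, all 30 genes kept their call and sign. That removal takes out 56.6% of the within-group variance, which makes a call easier to keep, so the kept calls say little about the gradient. The median ratio of the difference to the deposited one was 0.891, so for the median gene most of the difference did not lie along the gradient. Without the arrays at both ends of the gradient, a fit with fewer arrays, all 30 kept their sign but only 13 their call. Of the 30 genes, 0 had a group mean above the 99th percentile of gene values (11.39). Few genes lie above a 99th percentile in any case, so compression near the top of the array cannot be judged from this. Of 100 drawn splits of the irradiation labels within the lines, 2 gave at least 30 genes, the real one included. The other of these called 6764 genes. Of the 100 splits it had the largest difference in response of the gradient score, 29.5 against 18.7 for the real split. This points to the array gradient, although the splits at 26.9 and 26.8 gave 0 genes. Under other labels a real difference in response adds to the spread within groups and lowers the count, so the splits cannot exclude chance. A different response of the βCRISPR line is thus only a hypothesis for the 30 genes, and it was found on these data. Only 7 of the 30 genes kept their call without replicate 1 of the irradiated control group.

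Limma called 2.67 times as many genes between the unirradiated lines as between the irradiated ones. With the array gradient removed this ratio was 1.24, but mostly because the count between the irradiated lines rose, from 2987 to 5456. That between the unirradiated lines fell from 7974 to 6746. At 1.5-fold or more the counts went from 293 to 292 and from 468 to 309, so the gradient could account for part of the ratio. Leaving out 1 array moved the count between the unirradiated lines from 4492 to 10056 and that between the irradiated lines from 2192 to 3391. The gradient score within groups fell with the signal of 23 background probe sets (r = -0.917, exact permutation p = 0.00386 over 1296 arrangements; rho = -0.944, exact permutation p = 0.00309; 12 arrays, 1 relation), and r was -0.864 without the 2 arrays farthest from the median background. Background binding is thus a candidate explanation of the gradient within groups only. The loading on the gradient rose with a gene's mean level (Spearman 0.475), which may build in part of this relation. Background was 5.84, 5.76 and 5.83 in the unirradiated βCRISPR arrays and 5.88, 5.81 and 5.77 in the unirradiated control arrays. These overlapping levels do not account for the gap in score between these groups (-16.0, 1.28 and -22.5 against -3.81, 5.28 and 20.8). Smaller line differences after irradiation stay open: the slope of the differences after against without irradiation was 0.947 with the gradient removed and 0.715 as deposited, and leaving out 1 array moved the first between 0.834 and 0.963.

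The irradiated βCRISPR arrays carry a genotype label that reads wild type, against their titles and source names. Over 71 genes that differed at least 2-fold between the unirradiated lines, these arrays lay at 1.02, 0.970 and 0.994 on a scale from control (0) to βCRISPR (1), and the irradiated control arrays between 0.0394 and 0.0813. The lowest value, 0.970, argues against control cells in these arrays. How the label arose was not tested.

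Exon usage differed in response in 1330 genes by diffSplice and in 1 by the splicing index. The latter was KITLG, with a junction probe set shifted by -2.06 relative to the gene (adjusted p = 0.0145 by limma on the splicing index). That probe set itself differed by -0.50 in response, with group means of 7.27 to 7.74, so most of the shift is the gene's own difference of 1.66, which the probe set did not follow. The other genes among the 8 with the smallest diffSplice p did not pass by the splicing index. Their shifts were 2.20 in LRP1, 1.80 in MICALL1, 1.92 in WFDC2, -1.38 in APP, -1.24 in GNB2, 2.02 in KCNJ8 and -1.65 in WHSC1L1. Those of LRP1, WFDC2 and KCNJ8 had a group mean below the background (4.88, 4.78 and 4.57), so the size of their shifts is not exact. Of 30 drawn splits 10 gave at least 1330 genes, the highest other 4631, so chance cannot be excluded for this count. Leaving out 1 array moved it to 3334 and 848 (replicates 1 and 3 of the unirradiated control group), 841, 4354 and 303 (replicates 1, 2 and 3 of the unirradiated βCRISPR group), 509 and 506 (replicates 1 and 3 of the irradiated control group) and 825 and 797 (replicates 1 and 2 of the irradiated βCRISPR group). For the 12 probe sets, 1 of 40 splits did, the real one, with 0 as the highest other. That count was 0 and 2 without replicates 2 and 3 of the unirradiated control group, 4 and 44 without replicates 1 and 2 of the unirradiated βCRISPR group, 0, 7 and 0 without replicates 1, 2 and 3 of the irradiated control group, and 0, 6 and 0 without those of the irradiated βCRISPR group (limma; 55431 probe sets had an unadjusted p under 0.05 with all arrays).

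Camera called 13 lists for the difference in response, and 15 of 100 drawn splits gave as many, the highest other 15, so chance cannot be excluded. Their adjusted p values were 0.0101 for p53 targets of DNA repair and metabolism, 0.00338 for G1/S genes, 0.0022 for double-strand break repair, 0.00359 for the unfolded protein and integrated stress response, 0.0196 for hypoxia and glycolysis, 0.000998 for cholesterol synthesis and 0.0425 for oestrogen receptor targets. They were 0.00158 for splicing factors, 0.00335 for mesenchymal, 0.00624 for luminal and 0.00122 for immune cell markers, 0.0172 for ribosomal proteins and 0.0249 for reference genes. Leaving out 1 array ended 4 of these calls in several ways. The hypoxia list did not pass without replicate 2 of the unirradiated control group (0.0653), of the unirradiated βCRISPR group (0.0677) or of the irradiated control group (0.145), or without replicate 3 of the irradiated βCRISPR group (0.0587). Oestrogen receptor targets did not pass without replicates 2 and 3 of the unirradiated control group (0.0528 and 0.0785), replicates 1, 2 and 3 of the unirradiated βCRISPR group (0.0514, 0.0574 and 0.0587), replicate 1 of the irradiated control group (0.0599) or replicate 3 of the irradiated βCRISPR group (0.073). Ribosomal proteins did not pass without replicates 2 and 3 of the unirradiated control group (0.0528 and 0.0813), replicate 3 of the unirradiated βCRISPR group (0.136) or replicate 1 of the irradiated control group (0.127). Reference genes did not pass without replicates 2 and 3 of the unirradiated control group (0.0547 and 0.095), replicate 3 of the unirradiated βCRISPR group (0.0661) or replicate 3 of the irradiated βCRISPR group (0.0729).

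For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real count of genes and the highest other were 1400 and 0 for irradiation of the control line, 3381 and 0 for irradiation of the βCRISPR line, 7974 and 1184 between the unirradiated lines, and 2987 and 0 between the irradiated lines; 1 split, the real one, gave as many in each. For probe sets they were 10449 and 0, 28155 and 0, 102966 and 17489, and 35454 and 0, again with 1 split each. For exon usage they were 833 and 2064, with 3 splits as large, then 6116 and 2958, 9136 and 6987, and 2203 and 92, with 1 each. For gene lists they were 14 and 17 (3 splits), 11 and 13 (4 splits), 13 and 12 (1 split) and 5 and 9 (7 splits).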

How the results depend on the processing

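Removal of the array gradient, leaving out the arrays at its ends, leaving out haplotype probe sets and the splicing index were chosen after seeing the data; except where stated below the cause of a change was not tested. Over all settings, named genes kept their side of the threshold in 11583 cases. They passed anew in 265, no longer passed in 472 and reversed in 3. For gene lists these counts were 1614, 16, 121 and 9, and for named exon usage 789, 1, 8 and 0. Direction was compared only where the main fit or the alternative called the item. Uncalled values that changed sign thus count as kept. With array quality weights, whose estimate did not converge, limma called 5523 and 11545 genes for irradiation of the control and βCRISPR lines, 14036 and 5018 between the lines without and after irradiation, and 9710 for the difference in response. With the gradient removed it called 3635 for the control line, 5456 between the irradiated lines and 411 for the difference, and camera called 3 lists between the unirradiated lines and 5 for the difference. Without the arrays at both ends the counts were 2229 for the βCRISPR line, 3286 between the unirradiated lines and 14 for the difference. Asking for 1.5-fold, which by construction calls fewer, gave 204, 250, 468, 293 and 14, and fitting only the 2 unirradiated groups, which has fewer arrays, gave 4086. Without the filter the difference had 15 genes and 4 probe sets, the βCRISPR line 17644 probe sets, and exon usage 2421 genes in the control line, 4488 between the irradiated lines and 3338 for the difference. With a replicate block the difference had 11 genes and 0 probe sets by limma (12 without the block; 55431 probe sets had an unadjusted p under 0.05 without it). Exon usage with the filter at the 75th percentile was 3659 in the βCRISPR line, 1307 between the irradiated lines and 530 for the difference, and with exon probe sets only 4034 and 482 for the βCRISPR line and the difference. The splicing index gave 182, 733, 4852, 696 and 1. With an estimated correlation camera called 4, 3, 0, 0 and 0 lists, and fry 3 for the difference. The correlation of the responses was 0.783 over genes called in either line and 0.788 with the gradient removed.

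Leaving out 1 array gave 877 to 1712, 1599 to 7182, 4492 to 10056, 2192 to 3391 and 7 to 3640 genes for the control line, the βCRISPR line, the lines without and after irradiation, and the difference. In the same order it gave 6077 to 11105, 11418 to 63205, 47630 to 137482, 19353 to 38993 and 0 to 44 probe sets, and 451 to 1434, 1833 to 9057, 5039 to 10740, 1427 to 2787 and 303 to 4354 genes for exon usage. Lists ranged over 10 to 16, 10 to 12, 13 to 14, 4 to 6 and 9 to 14, and the correlation of the responses over 0.421 to 0.712. Reversed values in the βCRISPR line were those of IFIH1 (-0.18) and RAPGEFL1 (-0.03) with the filter at the 75th percentile and of S100A4 (0.01) with exon probe sets only, none of which passed there. With the gradient removed splicing factors reversed in the βCRISPR line (0.00827) and between the unirradiated lines (0.575). For the difference the lists of mitosis (2.14e-10), G1/S (0.2), double-strand break repair (0.464), splicing factors (0.238), ribosomal proteins (0.464) and reference genes (0.605) did so. Oestrogen receptor targets between the unirradiated lines reversed with fry (0.046). Signal over background limits TNFSF15 and SLC6A14 in the control line (4.77 and 5.69), which lay below the mean of the background probe sets. Values above this mean can be unspecific signal as well, so the size of other changes from low levels may be inexact too.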

Other observations

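The correlation of the gradient with the line difference across genes was chosen after the results were seen. Across genes, which are not independent replicates, the loading on the gradient had a correlation of -0.574 with the line difference without irradiation, of -0.0449 with that after irradiation, and of 0.778 with the difference in response. The shares of called genes that were higher in the unirradiated βCRISPR line were 56.6% as deposited, 45.2% with the gradient removed, 38.6% without the arrays at its ends and 63.6% with median centring. Of the 30 genes whose response differed, 19 (63.3%) had a smaller difference between the lines after irradiation than without it.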
